A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

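RNA was sequenced from cultures of Saccharomyces cerevisiae BY4742 treated with NaHS or left untreated, at an early stage (before 72 h after inoculation) or a late stage (after it), with 3 libraries in each of 4 groups. Per the labels, RNA was extracted with TRIzol, treated with DNase I, made into TruSeq libraries with size selection and PCR amplification, and read as pairs on a NovaSeq instrument. The submitters' notes name SeqPrep and Sickle for trimming, TopHat for alignment, Bowtie 0.12.2 and the R64 reference. The quantifier, its annotation and its use of strand are not given in the sources used here, so overlapping genes, antisense genes and near-identical copies are treated as uncertain. The labels do not say whether the libraries of a group came from separate cultures, and the NaHS dose is not given, so every p describes only the spread between these libraries.

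The authors deposited a table of expression values for each stage. The early table holds TPM (length-scaled transcript abundance with a fixed total), a unit read from its deposited values, whose column totals lay between 998109 and 998610. The late table holds FPKM (fragments scaled by gene length and library size) per the file headers, with column totals between 1510280 and 2145470. There were 7445 early and 7555 late entries, and 7126 identifiers were in both. Read counts were not analysed here, so the depth per library is unknown and no counting interval or detection floor can be given. The fixed plan had assumed counts for its first choice of test and named limma on log2 values for normalized tables, and that second choice was used. Because the tables carry different units and were normalized separately, late controls were not compared with early controls.

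Values were converted to log2 of the value plus 1. Genes with a mean of at least 1 over a comparison's libraries were tested. Entries that name no gene (319 early ENSRNA entries and 429 late TCONS entries) were left out of the tests. Each stage was fitted separately with limma 3.58.1 in R 4.3.3 (linear model, moderated test with a trend, 2-sided), NaHS minus control, and p was adjusted by Benjamini-Hochberg over all genes tested. A gene that rose or fell is one with an adjusted p below the threshold of 0.05, with no minimum change. For the difference between stages, limma was fitted to all 12 libraries with stage, treatment and their interaction, on genes with a mean of at least 1 in both tables, so that each table served as its own reference. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1, and by chance 10% of unchanged genes show no overlap between 3 and 3 values. Gene positions are those of the R64 reference annotation.

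A set of 37 gene lists was written before the data were examined. Apart from the list of hydrogen sulfide focus genes, 36 lists were open to test, and the 33 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera compares a list with the other genes. At the preset correlation it also called up to 12 early and 13 late lists when NaHS and control libraries were mixed in regrouping. It was repeated with the correlation estimated from the residuals, and fry was run beside it, which tests whether a list's genes move on balance to one side and compares them with no other genes. Counts of risen and fallen members were taken over all genes tested and again adjusted over the list alone. Genes were named by a rule fixed in advance: mean of at least 10, no overlap between the 3 and 3 values, and the 10 largest changes in each direction (5 for the difference between stages, without the overlap condition), with up to 2 risen and 2 fallen members of each list described and every focus gene. The rule was repeated without genes that had a 0 in any library after the zeros of the late table had been seen. No fold change is given for a gene with a 0 in the libraries compared.

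The alternatives tried were pseudocounts of 0.1 and 5, no low-value filter, a mean of at least 10, a minimum log2 change of 1, a block for the replicate number, each library left out in turn, the estimated correlation and fry. Median-ratio scaling, upper-quartile scaling, equal totals, genes with a 0 left out and entries without a gene kept were added after the data had been seen. The pipeline was tested on simulated data with the spread of the real tables. Of 100 genes moved by 1 on the log2 scale it recovered 63 in the early design, 38 in the late design and 21 for the difference between stages. Of 100 genes moved by 2 it recovered 94, 88 and 79, with 3, 4 and 7 unchanged genes called and none with the wrong sign. The simulated noise was independent between genes, and few genes were moved, in directions drawn at random. These counts therefore do not cover correlated genes or a shift of whole libraries.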

Results

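BY4742 is a haploid laboratory yeast of mating type alpha, and NaHS is a salt that releases hydrogen sulfide in water. The 12 libraries fell into 4 groups of 3: early control, early NaHS, late control and late NaHS, with the stages parted at 72 h after inoculation. The series asks whether hydrogen sulfide given late extends chronological lifespan, the survival of cells that have stopped dividing; survival itself was not among the deposited values. LEU2, LYS2 and URA3 were at 0 in all 12 libraries, while HIS3 lay between 301 and 345 TPM in the early ones. In the late table, 777 protein-coding genes were listed at 0 in all 6 libraries against 131 in the early table, and 271 of the 777 had an early mean of at least 10 TPM.

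The comparison within early cultures asks what NaHS changed while it was given before 72 h. The copper-binding metallothionein CUP1-2 (YHR055C, chromosome VIII, 214533 to 214718) rose from 1851 ± 882 to 27651 ± 8634 TPM (SD, n = 3 each), a log2 change of 3.95 (SE 0.387, limma adjusted p = 0.000926). BTN2, which sorts misfolded proteins, rose from 22.2 ± 1.04 to 242 ± 131 TPM, and CPR6, a partner of the Hsp90 chaperone, rose from 61.9 ± 9.09 to 339 ± 18.2 TPM. The water channel AQY1 fell from 802 ± 81.4 to 23.2 ± 11.6 TPM, a log2 change of -5.19. ADH2, the dehydrogenase that consumes ethanol, fell from 2876 ± 41.5 to 149 ± 99.2 TPM (adjusted p = 0.00305).

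Of 6124 genes tested in early cultures, 616 rose and 1743 fell, and 160 of the former and 775 of the latter moved by at least 1 on the log2 scale. In 3563 genes (58.2%, against 10% by chance) the 3 NaHS values did not overlap the 3 control values. Over all genes the median log2 change was -0.24, which median-ratio scaling moved to -0.0074 and upper-quartile scaling to 0.076. Median-ratio scaling called 2187 genes, 1063 higher and 1124 lower, of which 1740 were among the 2359, and upper-quartile scaling called 2152, 1201 higher and 951 lower, of which 1567 were. The 2359 calls dropped to 1425 without control 1, to 1392 without control 2 and to 1492 without control 3.

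The CUP1 repeat on chromosome VIII held most of the largest rises among genes without a 0. CUP1-1, the near-identical copy of CUP1-2, rose by 3.44 on the log2 scale, and how reads were shared between the copies is not known. The repeat's entries summed to 9.40%, 10.7% and 4.73% of the TPM in the NaHS libraries and to 0.719%, 0.628% and 0.582% in the controls. CRS5, a further copper-binding metallothionein, rose from 2123 ± 184 to 4552 ± 1064 TPM (adjusted p = 0.00542), whereas the copper-zinc superoxide dismutase SOD1 did not pass (log2 change of -0.24, adjusted p = 0.212). The SOD1 change was 0.017 with median-ratio scaling and 0.11 with upper-quartile scaling. Without NaHS 3, SOD1 was called lower (adjusted p = 0.00321). Entries for ribosomal RNA also took more of the NaHS libraries, at 1.70%, 1.44% and 3.20% against 0.872%, 1.18% and 0.757%.

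TKL2 (YBR117C, chromosome II, 474392 to 476437), a transketolase of the pentose phosphate pathway, had the smallest adjusted p of the early comparison, and its reads cannot be separated here from those of the overlapping YBR116C. It fell from 447 ± 7.20 to 13.2 ± 0.853 TPM, a log2 change of -4.99 (SE 0.0984, adjusted p = 9.1e-06). Catalase T (CTT1), which breaks down hydrogen peroxide, fell from 568 ± 53.0 to 32.4 ± 9.81 TPM. The eisosome-linked FMP45, the reticulon-like RTN2, the ammonium exporter ATO3, the biotin-precursor transporter BIO5 and the aldehyde dehydrogenase ALD6 fell by between 3.74 and 4.43 on the log2 scale. ZPR1, which helps fold a translation factor, rose from 70.0 ± 6.39 to 390 ± 108 TPM.

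**Figure D1:**
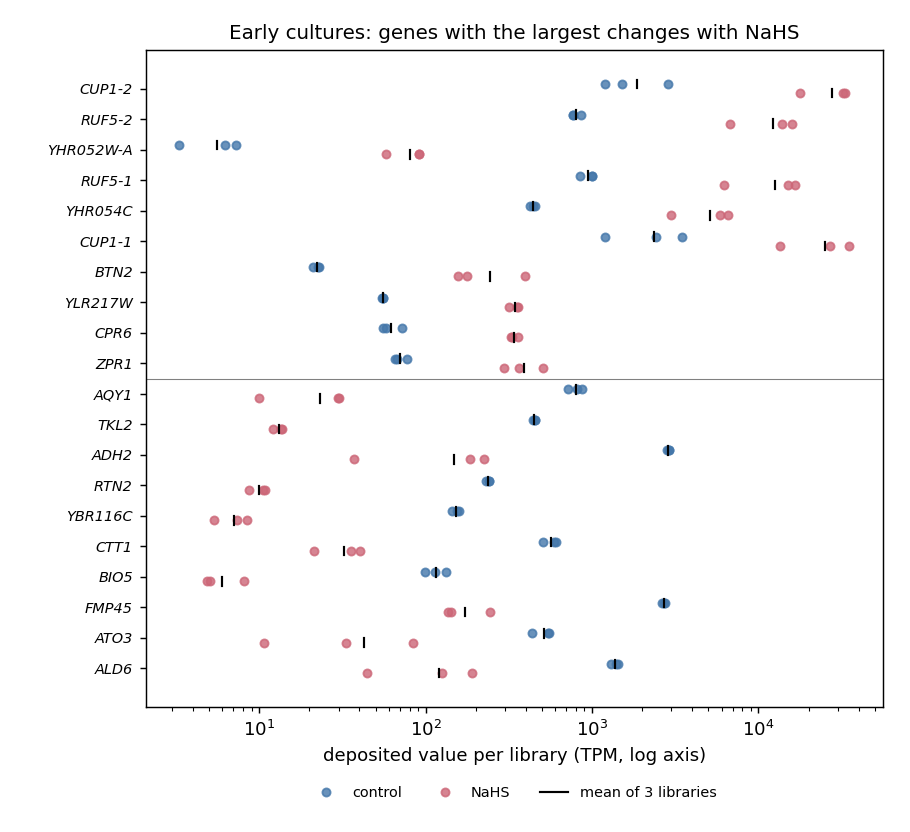
Deposited TPM on a log axis for genes without a 0 named by the fixed rule in early cultures, with a point for each of the 3 control and 3 NaHS libraries and a tick at the mean of 3. No NaHS point overlaps the controls, as the rule required, and AQY1 had means of 802 and 23.2 TPM.

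Heat shock genes rose as a group in early cultures. Of 30 heat shock and chaperone genes, 23 rose, 1 fell and 6 did not pass (24 and 1 adjusted over the list alone), with a limma camera adjusted p = 7.2e-17 and an adjusted p = 0.392 with an estimated correlation. Among 72 ribosome biogenesis genes, 13 rose, 3 fell and 56 did not pass (7 and 3 adjusted over the list alone; adjusted p = 1.7e-05, and adjusted p = 0.421 with an estimated correlation), and 20 rose with median-ratio and 23 with upper-quartile scaling. RLP7, which helps build the large ribosomal subunit, rose by 1.09 on the log2 scale, while UTP7, needed for small-subunit RNA processing, changed by -1.52. Respiratory chain and ATP synthase genes encoded in the nucleus also stood above the other genes, with 19 of 43 risen, 9 fallen and 15 not passing (19 and 9 adjusted over the list alone; adjusted p = 0.000203, and adjusted p = 0.342 with an estimated correlation). With median-ratio scaling 24 of them rose and 2 fell, and with upper-quartile scaling 26 and 2. COX7, a cytochrome c oxidase subunit, rose from 2892 ± 16.8 to 6691 ± 723 TPM, and QCR8, a subunit of the bc1 complex, rose by 1.22 on the log2 scale. NDE2, the external NADH dehydrogenase, changed by -3.09. COX4, a focus gene from the same complex as COX7, passed with a log2 change of -0.29 (adjusted p = 0.0443), which upper-quartile scaling turned to 0.061 (adjusted p = 0.736). COX4 also lost its call with median-ratio scaling (0.816) and without any control, NaHS 1 or NaHS 2 (up to 0.153).

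Genes for using non-sugar carbon and for storage carbohydrate fell. Among 29 genes of gluconeogenesis and non-fermentable carbon use, 22 fell, 1 rose and 6 did not pass (23 and 1 adjusted over the list alone; camera adjusted p = 0.000228, and adjusted p = 0.653 with an estimated correlation). Of 25 genes of the TCA and glyoxylate cycles, 17 fell and 8 did not pass (20 fell adjusted over the list alone; adjusted p = 0.000203, and adjusted p = 0.421 with an estimated correlation). MLS1, the malate synthase of the glyoxylate cycle, fell from 1529 ± 106 to 145 ± 85.1 TPM. Of 21 trehalose and glycogen genes, 17 fell and 4 did not pass (19 fell adjusted over the list alone; adjusted p = 0.000203, and adjusted p = 0.342 with an estimated correlation), among them SGA1, a glucoamylase, at -2.19 on the log2 scale. Of 29 general stress genes, 21 fell, 4 rose and 4 did not pass (22 and 4 adjusted over the list alone; adjusted p = 0.00438, and adjusted p = 0.421 with an estimated correlation), with the membrane-linked PNS1 at -3.36 and the wall protein SPI1 at 1.36 on the log2 scale.

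Lists of ergosterol, vacuolar protease, ribosomal protein and nitrogen genes stood below the other genes. Of 28 ergosterol genes, 19 fell, 1 rose and 8 did not pass (19 and 1 adjusted over the list alone; camera adjusted p = 0.0021, and adjusted p = 0.342 with an estimated correlation), and ERG13, which makes the precursor of mevalonate, fell from 58.4 ± 7.73 to 6.34 ± 2.55 TPM. Of 10 vacuolar protease genes, 6 fell and 4 did not pass (9 fell adjusted over the list alone; adjusted p = 0.00649, and adjusted p = 0.421 with an estimated correlation). Among 135 cytosolic ribosomal protein genes, 69 fell, 4 rose and 62 did not pass (71 and 6 adjusted over the list alone; adjusted p = 0.0033, and adjusted p = 0.869 with an estimated correlation), with RPL5 at -1.97 and RPS27A at 1.27 on the log2 scale. With median-ratio scaling 40 of these fell and 9 rose, and with upper-quartile scaling 32 and 9. The list did not pass without NaHS 2 (adjusted p = 0.0817). Of 28 genes under nitrogen catabolite repression, 12 fell, 1 rose and 15 did not pass (12 and 1 adjusted over the list alone; adjusted p = 0.029, and adjusted p = 0.653 with an estimated correlation), and without NaHS 3 the list had an adjusted p = 0.122. GAP1, the general amino acid permease, fell from 113 ± 1.17 to 10.51 ± 4.49 TPM, and MEP2, an ammonium permease, fell from 138 ± 35.4 to 12.3 ± 3.50 TPM. The other 22 lists did not pass camera as deposited. Fry called 23 early lists, of which 10 were among the 11 called by camera. By camera, the peroxisome list passed with median-ratio scaling (adjusted p = 0.0447), upper-quartile scaling (0.021) and without control 3 (0.047). The stationary phase list (0.0487) and the mitochondrial ribosome list (0.0344, above the other genes) passed with upper-quartile scaling, and the list for RNA polymerase I and III without control 3 (0.0287).

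Among called genes of sulfur metabolism more fell than rose in early cultures, where 73.9% of all calls fell. No sulfur list passed camera as deposited. Fry, which compares a list with no other genes, called sulfate assimilation (adjusted p = 0.000897), methionine and cysteine (0.00162) and glutathione and thioredoxin (0.000281) lower. Of the 23 lists fry called early, 21 were called lower, while the median gene changed by -0.24 on the log2 scale. These calls therefore do not set sulfur genes apart from the other genes. Of 33 glutathione and thioredoxin genes, 15 fell, 3 rose and 15 did not pass (camera adjusted p = 0.117). CYS3, which makes cysteine from cystathionine and can release hydrogen sulfide, fell from 51.5 ± 4.5 to 13.8 ± 2.39 TPM (log2 change of -1.84, adjusted p = 0.000582). CYS4, the step before it, fell from 129 ± 13.1 to 62.1 ± 3.23 TPM, and the sulfite reductase subunits MET10 and MET5 changed by -1.82 and -1.55 on the log2 scale. The sulfate permease SUL1 changed by -1.37 and the glutathione-making GSH1 by -1.11. MET17, which fixes sulfide into homocysteine, changed by -1.40 (adjusted p = 0.0166) but had an adjusted p = 0.0539 without control 3 and 0.0636 with upper-quartile scaling. The cystathionine lyase STR3 rose by 1.14 (adjusted p = 0.0249) and lost its call without each control in turn, with an adjusted p of up to 0.0811. Of 29 methionine and cysteine genes, 17 fell, 2 rose and 10 did not pass (17 and 3 adjusted over the list alone). The list did not pass (camera adjusted p = 0.0554, and adjusted p = 0.653 with an estimated correlation), though it did with median-ratio scaling (adjusted p = 0.026), upper-quartile scaling (0.0134) and without control 1 (0.0363) or control 2 (0.0362). HOM3, the first kinase on the way to homoserine, rose from 42.7 ± 4.56 to 88.1 ± 13.1 TPM (adjusted p = 0.00327). Of 10 sulfate assimilation genes, 5 fell, 2 rose and 3 did not pass (7 and 3 adjusted over the list alone; camera adjusted p = 0.393, and adjusted p = 0.784 with an estimated correlation).

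The 2 risen sulfate assimilation genes were MET14 and MET22, at 0.51 and 0.41 on the log2 scale. MET14 lost its call without control 1 or control 2 (adjusted p of up to 0.0678), and MET22 without any control or without NaHS 2 (up to 0.138). The sulfite exporter SSU1 and the sulfurtransferase TUM1 were called lower at -0.75 and -0.46. SSU1 lost its call without any control or without NaHS 1 (adjusted p of up to 0.109), and TUM1 without any control, NaHS 1 or NaHS 2 (up to 0.118). Both lost their calls with median-ratio and upper-quartile scaling (up to 0.114 for SSU1 and 0.644 for TUM1). STR2, MET16, MET3 and the cysteine desulfurase NFS1 did not pass (log2 changes of 0.57, 0.79, -0.57 and 0.11), nor did the chaperone-like HSP31 at 0.16. ATG8, a ubiquitin-like protein of autophagy, rose from 377 ± 25.6 to 570 ± 79.1 TPM (log2 change of 0.59, adjusted p = 0.0149) and lost its call without control 1 (0.0655) or control 3 (0.053). SIR2, the histone deacetylase studied in replicative ageing, fell from 13.8 ± 0.460 to 3.20 ± 0.693 TPM.

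The comparison within late cultures addresses the stage in the series title. ARO9 (YHR137W, chromosome VIII, 375709 to 377250), an aromatic aminotransferase, rose from 22.3 ± 13.2 to 1192 ± 290 FPKM (SD, n = 3 each), a log2 change of 5.88 (SE 0.532, limma adjusted p = 0.00103). HAP4, the activating subunit of the regulator of respiratory genes, rose from 6.94 ± 2.73 to 84.0 ± 11.9 FPKM, and ARN1, a siderophore transporter, rose from 190 ± 39.3 to 1647 ± 238 FPKM. SIP18 (YMR175W, chromosome XIII, 611016 to 611255), a small protein made on drying, fell from 1595 ± 708 to 12.3 ± 4.02 FPKM, a log2 change of -6.84 (SE 0.406, adjusted p = 0.000257). MET6, the methionine synthase, fell from 229 ± 104.9 to 1.75 ± 0.669 FPKM.

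Of 5344 genes tested in late cultures, 282 rose and 534 fell, and with upper-quartile scaling 408 rose and 497 fell. In 2064 genes (38.6%, against 10% by chance) the 3 NaHS and 3 control values did not overlap. The 816 calls dropped to 408 without control 3, to 413 without NaHS 1, to 450 without NaHS 2 and to 424 without NaHS 3. Entries for ribosomal RNA took 3.60% of late control 3, against 0.267% and 0.959% of the other late controls and 0.328%, 0.312% and 0.259% of the late NaHS libraries. Of the 816 calls, 99 were listed at 0 in some library. LEU1, the isopropylmalate isomerase of leucine synthesis, had 1087, 531 and 1215 FPKM in the controls and was listed at 0 in the 3 NaHS libraries, and MRS4, a mitochondrial iron carrier, was listed at 0 in the 3 controls with 58.9, 54.97 and 24.1 FPKM with NaHS.

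Among other genes without a 0 named by the rule, the plasma membrane protein MRH1, the transcription factor STP4 and the sodium-phosphate transporter PHO89 rose by 3.34, 3.23 and 3.01 on the log2 scale. ICL1, the isocitrate lyase of the glyoxylate cycle, fell from 436 ± 114 to 18.8 ± 0.792 FPKM. THI4, which makes the thiazole part of thiamine, fell from 254 ± 80.5 to 12.2 ± 0.869 FPKM, and SNZ3, of vitamin B6 synthesis, fell from 183 ± 18.3 to 14.5 ± 5.97 FPKM. BAT1, the mitochondrial branched-chain aminotransferase, fell from 7130 ± 1741 to 518 ± 20.5 FPKM, whereas its cytosolic counterpart BAT2 rose from 271 ± 19.8 to 1573 ± 310 FPKM. Each of these passed with any library left out.

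**Figure D2:**
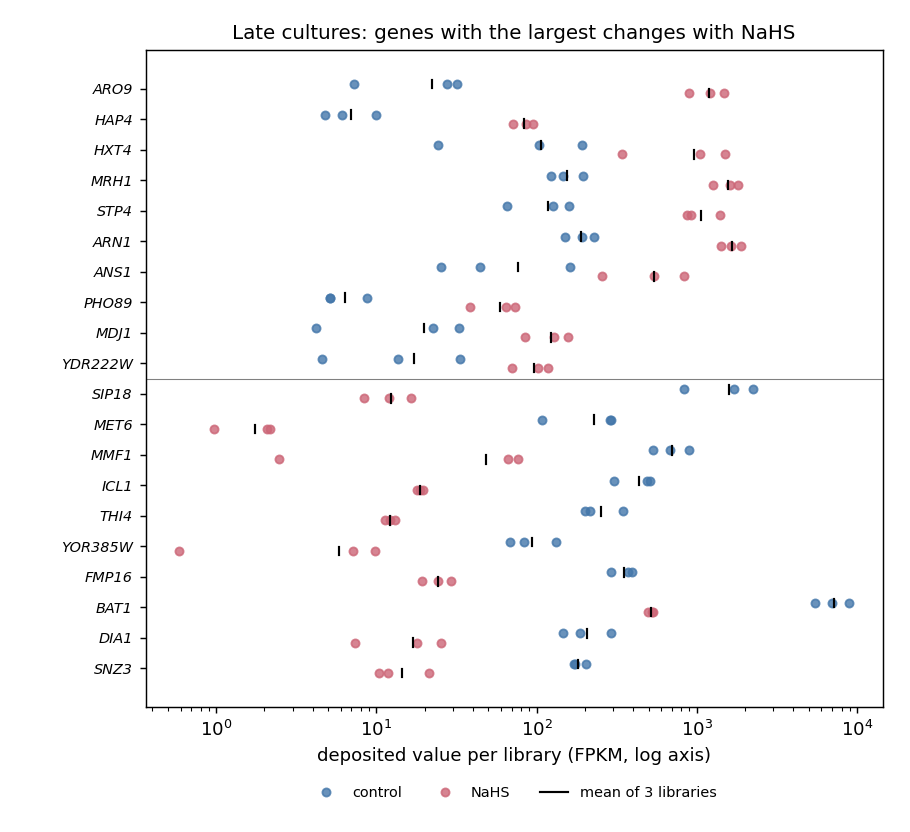
Deposited FPKM on a log axis for genes without a 0 named by the fixed rule in late cultures, with a point for each of the 3 control and 3 NaHS libraries and a tick at the mean of 3. ARO9 had the largest rise, at 5.88 on the log2 scale, and SIP18 the largest fall, at -6.84.

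Lists of sulfur and other amino acid genes stood below the other genes in late cultures. MET17 fell from 151 ± 58.9 to 15.9 ± 2.96 FPKM, and CYS3 fell from 602 ± 98.6 to 93.8 ± 3.78 FPKM (log2 changes of -3.11 and -2.66). SUL2, a sulfate permease, MET10 and STR3 changed by -3.07, -2.87 and -1.47 on the log2 scale, and CYS4 did not pass (log2 change of 0.94, adjusted p = 0.13). Of 28 methionine and cysteine genes, 15 fell and 13 did not pass (17 fell adjusted over the list alone; camera adjusted p = 6.98e-07, and adjusted p = 0.272 with an estimated correlation). Of 10 sulfate assimilation genes, 6 fell and 4 did not pass (7 fell adjusted over the list alone; adjusted p = 2.95e-05, and adjusted p = 0.272 with an estimated correlation). Of 33 glutathione and thioredoxin genes, 11 fell, 2 rose and 20 did not pass (14 and 3 adjusted over the list alone; adjusted p = 0.000779, and adjusted p = 0.272 with an estimated correlation), with the glutathione transferase GTT1 at -3.02 and the thioredoxin reductase TRR1 at 1.18 on the log2 scale. Among 56 other amino acid synthesis genes, 24 fell, 2 rose and 30 did not pass (31 and 4 adjusted over the list alone; adjusted p = 2.71e-08, and adjusted p = 0.272 with an estimated correlation), and LYS20, a homocitrate synthase, rose by 1.53 on the log2 scale.

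Energy and stress genes moved to both sides in late cultures. Of 43 respiratory chain and ATP synthase genes, 19 fell and 24 did not pass (27 fell and 1 rose adjusted over the list alone; camera adjusted p = 4.3e-09, and adjusted p = 0.276 with an estimated correlation). Of 25 TCA and glyoxylate genes, 10 fell, 1 rose and 14 did not pass (12 and 1 adjusted over the list alone; adjusted p = 1.93e-05, and adjusted p = 0.272 with an estimated correlation). Of 30 heat shock genes, 16 rose, 2 fell and 12 did not pass (20 and 3 adjusted over the list alone; adjusted p = 6.98e-07, and adjusted p = 0.272 with an estimated correlation), and HSP26, a small heat shock protein, fell from 2017 ± 480 to 431 ± 32.4 FPKM. Of 26 general stress genes, 14 fell, 1 rose and 11 did not pass (16 and 3 adjusted over the list alone; adjusted p = 2.66e-06, and adjusted p = 0.272 with an estimated correlation). CTT1 fell from 46.2 ± 14.9 to 3.03 ± 0.239 FPKM. Of 20 stationary phase genes, 6 fell and 14 did not pass (11 fell adjusted over the list alone; adjusted p = 1.93e-05, and adjusted p = 0.272 with an estimated correlation), among them the mitochondrial FMP16 at -3.82 on the log2 scale.

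Lists of iron, wall and ribosome assembly genes stood above the other genes, though most of their members did not pass. Of 31 iron regulon genes, 10 rose, 1 fell and 20 did not pass (14 and 1 adjusted over the list alone; camera adjusted p = 1.93e-05, and adjusted p = 0.272 with an estimated correlation). Of 33 cell wall genes, 9 rose, 1 fell and 23 did not pass (13 and 4 adjusted over the list alone; adjusted p = 0.00393, and adjusted p = 0.489 with an estimated correlation), with the wall proteins PST1 at 2.50, CWP2 at 2.07 and PIR3 at -2.40 on the log2 scale. Of 63 mitochondrial ribosome genes, 8 rose and 55 did not pass (8 rose adjusted over the list alone; adjusted p = 4.6e-06, and adjusted p = 0.272 with an estimated correlation), with 4 risen at equal totals and 11 with upper-quartile scaling. Ribosome biogenesis passed as a list although 1 of 80 genes rose and 79 did not pass (none adjusted over the list alone; adjusted p = 2.99e-06, and adjusted p = 0.543 with an estimated correlation). RNA polymerase I and III genes had 1 of 23 risen (none adjusted over the list alone; adjusted p = 0.00437, and adjusted p = 0.501 with an estimated correlation). With genes with a 0 left out, 4 ribosome biogenesis genes rose and 4 cell wall genes fell.

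Several further lists passed although at least 5 in 10 of their members did not. Of 10 vacuolar protease genes, 5 fell and 5 did not pass (6 fell adjusted over the list alone; camera adjusted p = 0.000817, and adjusted p = 0.272 with an estimated correlation), with PBI2, an inhibitor of a vacuolar protease, at -3.03 on the log2 scale. Of 35 proteasome genes, 2 fell, 1 rose and 32 did not pass (1 fell adjusted over the list alone; adjusted p = 0.000413, and adjusted p = 0.272 with an estimated correlation), and the catalytic subunit PRE3 changed by -1.18. Of 25 ergosterol genes, 5 fell and 20 did not pass (5 fell adjusted over the list alone; adjusted p = 0.01, and adjusted p = 0.272 with an estimated correlation). Of 28 genes under nitrogen catabolite repression, 10 fell, 3 rose and 15 did not pass (13 and 5 adjusted over the list alone; adjusted p = 0.0423, and adjusted p = 0.556 with an estimated correlation), with the GABA permease UGA4 at -1.71. Peroxisome genes had 7 of 28 fallen and 21 not passing (8 fell adjusted over the list alone; adjusted p = 0.0445, and adjusted p = 0.272 with an estimated correlation), and 132 cytosolic ribosomal protein genes had 2 risen, 1 fallen and 129 not passing (none adjusted over the list alone; adjusted p = 0.0267, and adjusted p = 0.742 with an estimated correlation). The nitrogen list lost its call without control 1 (adjusted p = 0.0553), control 3 (0.0799), NaHS 2 (0.069) or NaHS 3 (0.178) and with median-ratio scaling (0.0539). The peroxisome list lost it without control 2 (adjusted p = 0.0568), control 3 (0.0799), NaHS 2 (0.054) or NaHS 3 (0.0912), and the ribosomal protein list without control 3 (0.284) or NaHS 3 (0.329). Equal totals left 3 ergosterol genes fallen, 5 proteasome genes fell with genes with a 0 left out, and 5 ribosomal protein genes rose with upper-quartile scaling.

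The other 13 late lists did not pass camera as deposited, and of these fry called superoxide and peroxide defence lower (adjusted p = 0.0252). With upper-quartile scaling the lists for superoxide and peroxide defence, hypoxia and phosphate passed camera (adjusted p = 0.0498, 0.0492 and 0.0497). The first also passed without control 1 (0.0314) and with genes with a 0 left out (0.0202), and the hypoxic list with genes with a 0 left out (0.0231) and without NaHS 1 (0.0265) or NaHS 2 (0.0411). The phosphate list passed at equal totals (0.049) and without control 2 (0.0457) or NaHS 1 (0.0262).

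Among the remaining focus genes in late cultures, MET16, MET5 and COX4 changed by -1.54, -1.75 and -1.03 on the log2 scale. MET16 lost its call without control 3 or NaHS 1 (adjusted p of up to 0.057), MET5 without control 3 or any NaHS library (up to 0.0777), and COX4 without control 3, NaHS 1 or NaHS 3 (up to 0.0624). SIR2 did not pass (12.2 ± 0.666 and 13.2 ± 3.14 FPKM, adjusted p = 0.825), nor did ATG8 (118.6 ± 24.6 and 128 ± 49.8 FPKM, adjusted p = 0.904). STR2, MET3, SUL1, SSU1, NFS1, TUM1, HSP31, SOD1 and GSH1 did not pass either, with adjusted p values between 0.0907 and 0.987.

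**Figure D3:**
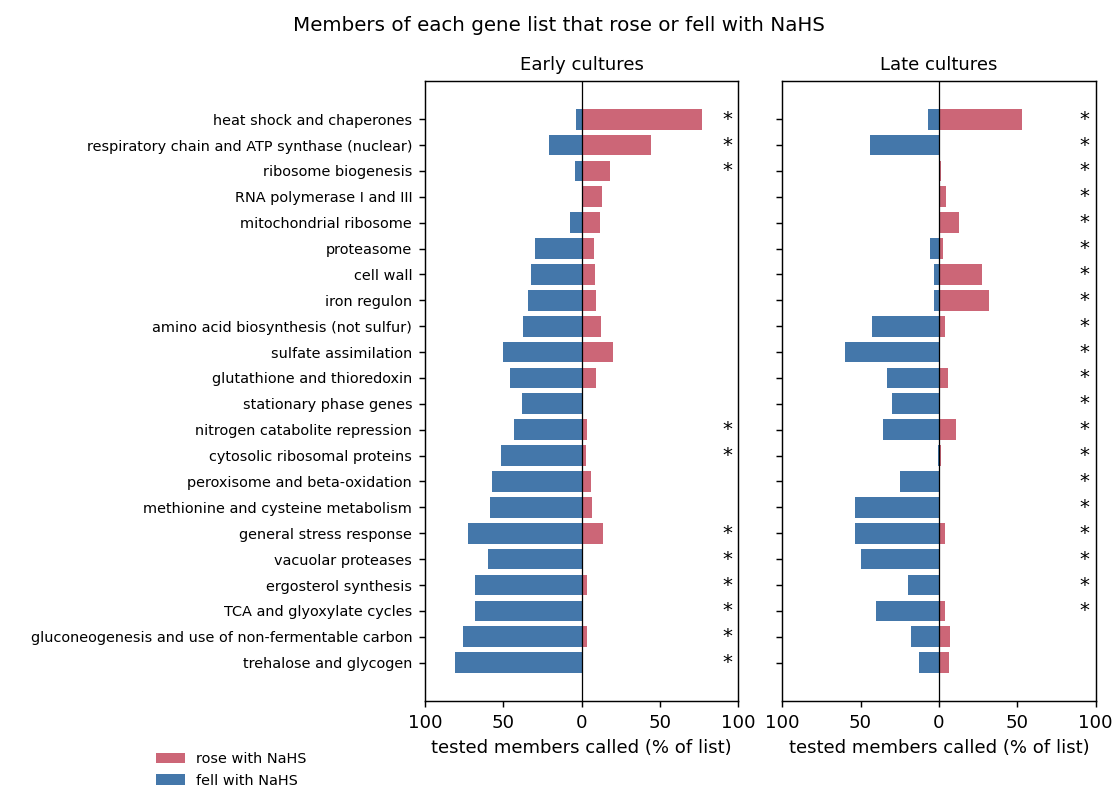
Percent of each gene list's tested members that rose (bars to the right of 0) or fell (bars to the left) in early and late cultures, with a star where the list passed limma's camera at the preset correlation of 0.01. Of the respiratory chain genes, 19 of 43 rose and 9 fell early, and 19 fell late.

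The difference between the stages was tested directly, as the late change minus the early change in each of 5165 genes. Stage went together with the unit (TPM early, FPKM late) and with the set of entries. A difference that comes from quantification therefore cannot be told apart from one of stage. The fit used a spread shared by both stages, although the median SE of the separate fits was 0.173 early and 0.239 late. ARO9 differed by 8.31 on the log2 scale, ARN1 by 4.77, and FIT2, a wall protein that retains siderophore iron, by 4.73. SIP18 differed by -6.76 and CUP1-2 by -4.04. CYS4 and SIR2, both lower early, differed by 1.98 (adjusted p = 0.00676) and 1.91 (adjusted p = 0.000725). HSP26, a small heat shock protein chosen here after its values were seen, differed by -2.23 on the log2 scale (adjusted p = 0.000725).

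In all, 1177 genes differed, 787 above 0 and 390 below, over a median difference of 0.25, and median-ratio scaling gave 54.0% below and upper-quartile scaling 50.1% below in place of 33.1%. Without early control 3 the count was 782. The 2 changes had opposite signs in 794 of the 1177 genes. Picking genes for a large difference favours opposite signs, so this count does not show a general reversal. Of genes called in both stages, 57 rose and 307 fell in both, while 18 and 47 went opposite ways. Of the 1177 genes, 613 were called in early cultures only, 241 in late cultures only, 184 in both and 139 in neither.

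Respiratory chain genes had the smallest adjusted p of the lists, with 27 of 43 below, 2 above and 14 not passing (27 and 2 adjusted over the list alone; camera adjusted p = 8.5e-15, and adjusted p = 0.453 with an estimated correlation), among them COX7, chosen after its values were seen, at -2.18 on the log2 scale. Amino acid synthesis genes had 20 of 56 below and 5 above (24 and 6 adjusted over the list alone; adjusted p = 4.28e-07, and adjusted p = 0.233 with an estimated correlation), methionine and cysteine genes 10 of 28 below and 4 above (10 and 4 adjusted over the list alone; adjusted p = 0.00338, and adjusted p = 0.453 with an estimated correlation), and sulfate assimilation genes 4 of 10 below and 1 above (5 and 1 adjusted over the list alone; adjusted p = 0.00403, and adjusted p = 0.453 with an estimated correlation). Heat shock genes had 7 of 30 below and 1 above (7 and 1 adjusted over the list alone; adjusted p = 0.00166, and adjusted p = 0.453 with an estimated correlation), and proteasome genes 1 of 35 below (none adjusted over the list alone; adjusted p = 0.00518, and adjusted p = 0.5 with an estimated correlation). Stationary phase genes had 5 of 20 below and 2 above (5 and 2 adjusted over the list alone; adjusted p = 0.0162, and adjusted p = 0.453 with an estimated correlation), and had an adjusted p = 0.0542 without late control 2. Hypoxic genes had 7 of 20 below and 1 above (7 and 1 adjusted over the list alone; adjusted p = 0.0328, and adjusted p = 0.453 with an estimated correlation), with an adjusted p = 0.0776 with median-ratio scaling, 0.0528 without early NaHS 2, 0.0552 without late control 2 and 0.0713 without late NaHS 3.

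Among lists above 0, cytosolic ribosomal proteins had the smallest camera p but not the largest difference (median of 0.68, against 1.62 for gluconeogenesis and 1.43 for the iron regulon), with 50 of 132 above and 3 below (56 and 3 adjusted over the list alone; camera adjusted p = 1.07e-05, and adjusted p = 0.698 with an estimated correlation). Iron regulon genes had 16 of 30 above and 1 below (17 and 1 adjusted over the list alone; adjusted p = 0.000416, and adjusted p = 0.453 with an estimated correlation), gluconeogenesis genes 15 of 28 above and 2 below (16 and 2 adjusted over the list alone; adjusted p = 0.00126, and adjusted p = 0.5 with an estimated correlation), and cell wall genes 15 of 30 above and 2 below (16 and 2 adjusted over the list alone; adjusted p = 0.00215, and adjusted p = 0.453 with an estimated correlation). Trehalose and glycogen genes had 8 of 16 above and 1 below (11 and 1 adjusted over the list alone; adjusted p = 0.0121, and adjusted p = 0.453 with an estimated correlation), and cell cycle genes 8 of 22 above (9 above adjusted over the list alone; adjusted p = 0.0184, and adjusted p = 0.453 with an estimated correlation). Mitochondrial ribosome genes had 11 of 63 above (9 above adjusted over the list alone; adjusted p = 0.0172, and adjusted p = 0.698 with an estimated correlation), with an adjusted p = 0.0583 when genes with a 0 were left out, 0.0599 without early NaHS 3 and 0.0793 without late NaHS 1. Median-ratio scaling put 34 ribosomal protein genes, 5 trehalose and glycogen genes, 4 cell cycle genes and 3 mitochondrial ribosome genes above 0, and upper-quartile scaling 31, 5, 5 and 4. Below 0, proteasome genes numbered 6 with median-ratio scaling. Equal totals put 13 amino acid synthesis genes, 6 methionine and cysteine genes and 3 stationary phase genes below 0.

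The other 18 lists did not pass camera for the difference as deposited. Fry called 19 lists for the difference, of which 13 were among the 15 called by camera. The general stress list passed camera at equal totals (adjusted p = 0.0494) and without early control 1 (0.0466), early control 2 (0.0475), early NaHS 1 (0.0411), late control 1 (0.0202), late NaHS 1 (0.0423) or late NaHS 2 (0.0383). The phosphate list, which fry called as deposited (0.00267), passed camera without late NaHS 1 (0.0388).

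Across genes tested in both stages, which are not independent replicates, the early and late changes had a Pearson r of 0.242 and a Spearman rho of 0.275. Both stages raised 57 genes (28.6 for independent lists) and lowered 307 (156.7 for independent lists). In 18 genes a rise early met a fall late (54.2 for independent lists), and in 47 a fall early met a rise late (82.8 for independent lists). The respiratory regulator HAP4 was higher in both, and CTT1, MET6 and CYS3 were lower in both.

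**Figure D4:**
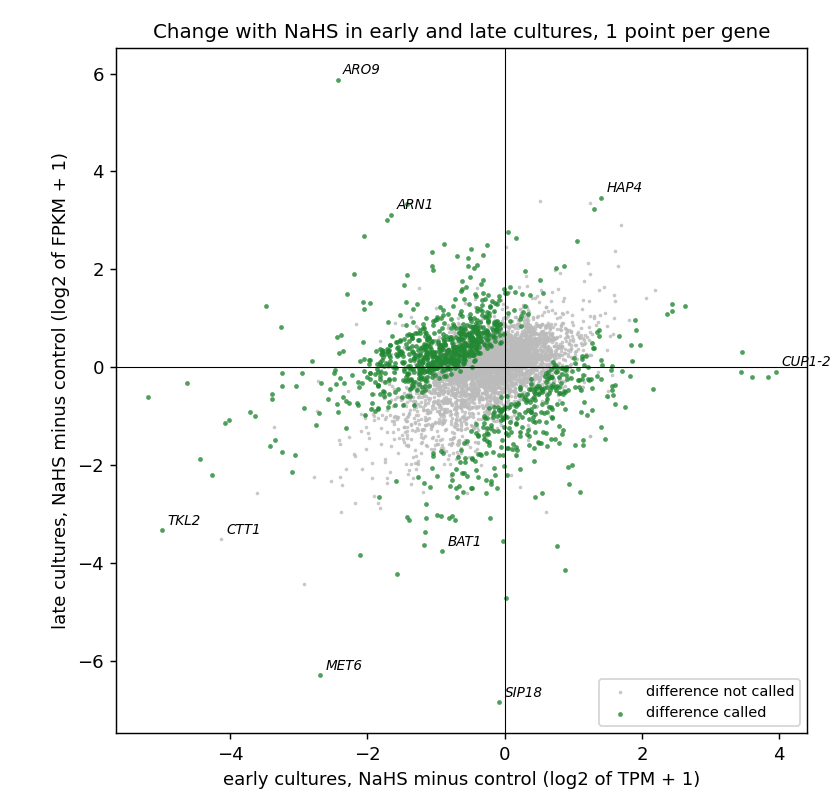
Early log2 change on the x axis against late log2 change on the y axis for 4791 genes without a 0 in any library, with a point per gene and the 1083 genes whose change differed between stages marked. ARO9 lies at a late change of 5.88 and SIP18 at -6.84.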

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

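The tests on zeros, on the balance of the early calls and on the CUP1 repeat were chosen only after those results were seen, while the counts over other groupings of the libraries were planned before the data were examined. The effect of NaHS was tested for a difference between late and early cultures, and 1177 genes differed, with stage not separable from unit and quantification. By list, the median late minus early difference (log2) was -1.17 for the respiratory chain and ATP synthase, -0.62 for amino acid synthesis, -0.43 for methionine and cysteine metabolism, -0.82 for sulfate assimilation, -0.33 for heat shock, -0.33 for stationary phase genes, -0.24 for the proteasome and -0.037 for hypoxic genes. It was 0.68 for cytosolic ribosomal proteins, 1.43 for the iron regulon, 1.62 for gluconeogenesis, 0.99 for the cell wall, 0.86 for trehalose and glycogen, 0.58 for the mitochondrial ribosome and 0.73 for the cell cycle. By gene it was 8.31 for ARO9, 4.77 for ARN1, 4.76 for MRH1, 4.73 for FIT2, 4.73 for CWP1, -6.76 for SIP18, -5.02 for YOR385W, -4.74 for MMF1, -4.40 for DIA1 and -4.04 for CUP1-2. MMF1 lost its call without each early control in turn, with an adjusted p of up to 0.0532. Of the genes with a 0 in some library, the difference had an adjusted p of 5.51e-06 for MRS4, 0.00173 for ALD6, 3.41e-05 for YGR259C, 1.84e-05 for ARO10, 5.16e-06 for LEU1, 7.22e-05 for ALD5, 8.08e-07 for AAC1 and 8.08e-07 for HMF1.

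Entries that name no gene, which the comparisons left out, took a mean of 0.886% of the early NaHS totals against 0.541% of the control totals. Of the 22 such entries tested early, 2 rose and 3 fell with NaHS, and of the 385 tested late, 20 rose and 25 fell.

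Among the late calls, 90 protein-coding genes had a 0 in some library, and 62 of them (68.9%) lay next to a protein-coding gene that also had a 0, against bounds of 15.6% and 33.3% over 10000 equal-sized random sets of tested genes. The random sets were drawn from all tested genes, most of which had no 0. Of all late protein-coding genes at 0 in some libraries, 62.3% had such a neighbour. It was 69.6% for those at 0 in all 6 and 22.4% for those without a 0. The excess thus goes with having a 0 and is not particular to the NaHS calls. Neighbouring genes merged or dropped together in the quantification would give such clusters of zeros. Of the 90 called genes, 87 were tested early, and 29 of these were called in the same direction there. That is more than the 27 that bounded the random sets. A response to NaHS that the early cultures also show thus stays open for part of them. The share was 33.3% for these genes and 47.1% for late calls without a 0. Both explanations may hold together. Of the 20 late genes at 0 in a whole group, MET28, AAC1 and ARO10 had no neighbour with a 0. MET28 also fell early (limma adjusted p = 0.000495), AAC1 did not pass there (0.131), and ARO10 was called in the opposite direction (0.00466). The other 17 had such a neighbour. Of these, AYR1, YER152C, PEX4, GAD1, YMR315W, SAM3 and GRE1 also fell early and HSP78 also rose. COX6 and MRS4 were called early in the opposite direction. LEU1 (limma adjusted p = 0.604), HMF1, RTA1, PUS6, YPK2, EFM6 and GAC1 did not pass early.

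Of the early calls 73.9% lay below the controls. The CUP1 repeat and ribosomal RNA took more of each NaHS library, which lowers every other gene in a unit with a fixed total. With totals taken without those entries, 60.5% of 2220 calls were lower, and 58.4% to 64.3% with a library left out in turn. These entries thus do not account for the whole imbalance of the values as deposited. Without control 1 that fit called 1300 genes, without control 2 1256 and without control 3 1264. The imbalance itself depended on the scaling: 51.4% of calls were lower with median-ratio scaling and 44.2% with upper-quartile scaling. Those scalings set a middle or upper value equal between libraries, so they cannot tell a true shift of most genes from one of scale. No biological explanation of the imbalance was tested, and the total RNA per cell, which these tables do not hold, stays open.

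The CUP1 repeat rose in the early NaHS libraries. Reads shared between the near-identical copies would move signal within the repeat. Its summed entries took 4.73% in the lowest NaHS library and 0.719% in the highest control. Each entry of the repeat rose, by between 3.44 and 3.95 on the log2 scale, so a higher sum followed from the pattern itself and is no separate test. Moving reads within the repeat alone would not raise every entry, but how far each copy rose stays unknown. A copper response through the regulator Ace1 was assumed, after the values were seen, to raise both of its targets CRS5 and SOD1. Of CRS5 and SOD1, 1 rose. For the CUP1 repeat a copper response through Ace1 and other routes cannot be told apart with so few targets. Of the other copper genes examined after the values were seen, CUP2, which encodes Ace1, rose by 0.86 (adjusted p = 0.0149, up to 0.0573 without each control in turn) and MAC1 by 0.56 (adjusted p = 0.0148, up to 0.0641 without control 2 or control 3), while the uptake genes CTR3 (-0.89, adjusted p = 0.0339) and FRE7 (-0.62, adjusted p = 0.0226) fell and lost their calls with median-ratio scaling (0.0813 and 0.0647), upper-quartile scaling and single libraries left out (up to 0.105 without control 2 and 0.0848 without control 1), and CTR1 and FRE1 did not pass (adjusted p = 0.453 and 0.985). Without early NaHS 3, CTR1 was called higher (log2 change of 0.75, limma adjusted p = 0.0101). Copper in the medium or cells was not measured.

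In early cultures 1 of the 10 groupings of the 6 libraries into 3 and 3, the real one, called as many as 2359 genes, and the highest other called 3. For the lists 2 of the 10 called as many as the real 11, and the highest other called 12. In late cultures 1 of the 10 groupings called as many as 816 genes (highest other 2), and 1 of the 10 as many as 20 lists (highest other 13). With 10 groupings the splits are too few for a share under 0.05. Every other grouping mixes NaHS and control libraries, so any effect of NaHS enters the spread and lowers the count of genes. The gap between the real count and the others therefore adds no support. For the lists, the early count does not mark the real grouping. A mixed early grouping called 12 lists with 0 genes, and a mixed late grouping called 13 lists with 2 genes. A mixed grouping still keeps part of the effect of NaHS, because it divides the NaHS libraries unevenly. These counts therefore cannot tell how many lists camera would call without any effect.

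For the difference between stages, 2 of 100 drawn groupings called as many as 1177 genes (highest other 1953), and 11 of 100 called as many as the real 15 lists (highest other 20). These counts do not decide whether chance gives such a difference, because regrouping the labels tests for no effect of NaHS at all and not for equal effects in both stages, and a grouping that mixes the labels adds the effect of NaHS to the spread between libraries. The grouping with 1953 genes swaps NaHS and control in the late cultures alone, which tests the sum of the early and late effects. The set of drawn groupings changed when a test that drew random numbers before it was replaced, so all 200 possible groupings were then counted as well. Among these, 2 called as many genes, with 743 as the highest apart from the swapped one, and 21 called as many lists.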

How the results depend on the processing

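The tests under median-ratio scaling, upper-quartile scaling, equal totals, genes with a 0 left out and entries without a gene kept were chosen only after the data were seen. A minimum log2 change of 1 left 935 of the 2359 early calls, as its construction requires. With each library left out in turn, the calls ranged from 1392 to 3267 in early cultures, from 408 to 840 in late cultures and from 782 to 1296 for the difference between stages, and the correlation of the early and late changes from 0.212 to 0.275. The early count was lowest without early control 2 (1392), and it fell to 1425 without control 1 and 1492 without control 3; the late count was 408 without control 3, 413 without NaHS 1, 450 without NaHS 2 and 424 without NaHS 3; and the count of differences was 782 without early control 3. A fit on fewer libraries has less power, and the cause of the higher count without early NaHS 3 (3267) was not tested. The correlation was 0.29 with genes with a 0 left out, and the cause was not tested. With an estimated correlation, 0 early lists, 0 late lists and 0 lists for the difference between stages passed limma's camera, with smallest adjusted p values of 0.342, 0.272 and 0.233. Fry, which asks a different question of each list, called 23 early lists against 11 by camera, 17 late lists against 20 and 19 lists for the difference between stages against 15, and the cause was not tested.

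COX4 in early cultures went from a log2 change of -0.29 to 0.061 with upper-quartile scaling, which moved the median of all genes. Over all alternatives, 2063 of 2255 values of the 142 named early genes kept their direction and side of the threshold, 173 lost the call and 18 gained it. In late cultures 1758 of 1956 values of 125 genes kept both and 196 lost the call. For the difference between stages 367 of 370 values of 18 genes kept both. Many of the named genes were picked for large called changes, so these shares do not stand for all calls. Of all early calls, 58.4% were kept without early control 2, and of all late calls 47.8% without late control 3. A block for the replicate number gave 1860 early calls, 487 late calls and 839 differences between stages, and the cause was not tested. Deviations of libraries with the same number correlated at -0.035, -0.011 and -0.028 early and at -0.11, 0.086 and 0.041 late, so the numbers were not taken as pairs. Count-based tests, other count scalings, filters on counts, a joint count fit of the 12 libraries, the comparison of late with early controls and the authors' own calls were planned and not run, because the tables hold normalized values. The depth of the libraries is unknown, so what it limits cannot be stated.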

Other observations

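The gene groups described here were all chosen after the values were seen, so their counts are descriptions and not tests. All 5 genes of biotin synthesis and uptake fell in early cultures, where the biotin synthase BIO2 fell from 273 ± 19.4 to 25.2 ± 7.91 TPM (SD, n = 3 each) and the biotin transporter VHT1 changed by -3.24 on the log2 scale, and 4 of 5 fell in late cultures, where VHT1 did not pass. Of 19 thiamine and vitamin B6 genes tested late, 8 fell and none rose, among them SNZ2 from 158 ± 25.0 to 18.1 ± 4.56 FPKM, and 6 of 22 fell early. Of 14 purine synthesis genes, 11 fell in late cultures, 2 of them listed at 0 in some library, and ADE1 went from 523 ± 173 to 167 ± 68.7 FPKM. In early cultures 6 of the 14 fell, and 2 with median-ratio scaling.

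Of 11 genes for leucine, isoleucine and valine, 9 fell in late cultures, with LEU1 listed at 0 in the NaHS libraries, and 1, the aminotransferase BAT2, rose, while 7 of the 11 fell and 1 rose early. The mitochondrial carrier OAC1 fell from 1167 ± 285 to 135 ± 21.0 FPKM, and ILV5 and LEU4, of the same pathway, changed by -2.56 and -2.23 on the log2 scale. In the pathway that turns amino acids into fusel alcohols, 3 of 7 genes rose late (ARO9, BAT2 and ARO10, the last listed at 0 in the 3 controls) and 1 fell, while 7 of 8 fell and 1 rose early. Of 5 genes for small proteins linked to drying, 4 fell and 1 rose late, with HSP12 at -3.12 on the log2 scale and GRE1 listed at 0 in the 3 NaHS libraries beside a neighbour with a 0. In early cultures 2 of the 5 fell, and 1 with median-ratio scaling. Of 17 genes for mitochondrial protein import and chaperones, 6 rose and 2 fell early (9 and 1 with median-ratio scaling), and of 15 tested late 3 rose, 2 of them (MGE1 and HSP78) listed at 0 in some library.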
